A study of Mus musculus with 6 samples.

How the data were processed

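RNA from C3H10T1/2 cells, which the labels call a mesenchymal stem cell line, was measured on 6 Affymetrix mouse expression arrays, 3 from cells given a GFP adenovirus and 3 from cells given a BMP9 adenovirus. Per the labels' protocols, cells were kept in medium with 0.5% serum for 30 h, and total RNA was labelled with biotin. Groups and replicate numbers came from the sample labels. Nothing in the labels says that the 3 arrays of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical.

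The deposited table held 1 intensity per probe set and array on a linear scale, and MAS5 is the tool named in the submitters' processing notes; its settings are not given in the sources used here. The mean of each array's intensities between the 2nd and 98th percentile lay close to 500, so the arrays had been scaled to a common level before deposit, as the values themselves show. MAS5 subtracts mismatch probes and leaves low signals imprecise. No detection calls were used here. The table held 22690 probe sets. Of these, 64 were controls and were left out, 20380 named 1 gene in the platform annotation, 691 named several and 1555 were unnamed here. Symbols were updated through Entrez identifiers with a RefSeq gene table of assembly GRCm38.p6, which held 20351 of the one-gene probe sets and not the other 29; no coordinates were used. The one-gene probe sets stood for 12393 genes.

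Signals were taken as log2(signal + 10.6), the offset being the 10th percentile of all values, so that log2 and fold changes understate the change of low signals. A probe set was tested where at least 3 of the 6 arrays reached the array's own 40th percentile, which lay between 98.76 and 118.16. This left 13812 probe sets, of which 12717 named 1 gene, and 8003 genes. Each gene stood by its tested probe set with the highest mean over the 6 arrays; 3078 genes had 2 or more. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, no block), two-sided, and p-values were adjusted by Benjamini-Hochberg over all tested probe sets at a threshold of 0.05. At that threshold 338 probe sets passed, 180 higher and 158 lower. Of the called genes 93 had 2 or more tested probe sets; in 25 all passed, in 2 (Gp1bb and Nit1, named after their values were seen) the sign differed, and in 0 were probe sets called in opposite directions. Errors beside signals are SD over 3 arrays, and errors beside log2 changes are SE from the fit. Where all 3 arrays of a group lay below the 40th percentile, the change is given as at least the fold against that percentile.

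Gene lists were tested with camera (preset correlation 0.01) on 1 value per gene, adjusted over the lists, with camera at an estimated correlation and fry as alternatives. Of 32 lists written before the data were examined, 31 had at least 5 tested members; 847 of the 929 list members had a probe set and 540 were tested. Preset camera called 6 lists, of which the unfolded protein response and the BMP/Smad targets also held with an estimated correlation; fry, which asks whether a list moves on balance one way, called these and the osteoblast markers. The design, the lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule took the 15 largest increases and the 15 largest decreases in fitted log2 change among called genes with separated groups whose higher group mean was at or above the median of that group's array medians, skipping RIKEN, EST and predicted names. It added up to 3 called members per direction of each list, or the 2 with the smallest p where none was called, and a fixed set of BMP, lineage and reference genes where measured.

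Replicate numbers were checked for pairing from the data before the fits were compared. Deviations from the group mean correlated by 0.534 between the replicate 1 arrays, 0.129 between the replicate 2 arrays and 0.134 between the replicate 3 arrays. Each pair thus exceeded the limit of 0.1 by which the numbers were to be taken as pairs. GFP replicate 2 deviated more closely with BMP9 replicate 3 (0.346) and GFP replicate 3 with BMP9 replicate 2 (0.317), and the labels give no reason for a pairing. Deviations cancel out within a group, so the shared deviation of the replicate 1 arrays alone raises the average correlation among the other arrays of both groups. The values for replicates 2 and 3 are therefore no evidence of a pairing, and fits with the block serve only as alternatives. Values with the replicate number as a block are given where they change a call or move a count by over 1.5 times. No pair of arrays within a group shared more than 0.339% identical values.

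Alternatives covered the offset, quantile normalization, median centring, cyclic loess, the filter, the variance model, array weights, the replicate block, each array left out in turn, the mean over a gene's probe sets and limma's treat at 1.5-fold. Leaving out both replicate 1 arrays was added after the data were seen. The fit was tested on simulated data in 5 runs of the comparison of BMP9 against GFP, each over 13812 probe sets with 200 changed: without the block it recovered 1.58% of changes of 1.5-fold, 31.7% of 2-fold and 93.3% of 4-fold, with 0 false among 423 calls. With the block it recovered 38.8%, 86.8% and 100%, with 6.46% of its calls false. A list shifted by 0.5 on the log2 scale was called in 5 of the 5 runs. The simulated arrays took their replicate effects and their spread from the fit with the block, so the comparison of both fits favours the block. Noise was drawn independently for each probe set, so the runs do not test camera on lists whose genes move together. The number of arrays limits the precision of every value.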

Results

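Transcripts were measured in C3H10T1/2 cells, a mouse line of multipotent mesenchymal character, after transduction with an adenovirus carrying either bone morphogenetic protein 9 (BMP9) or green fluorescent protein (GFP). BMP9, the product of Gdf2, is a secreted ligand of the BMP family that signals through the receptor Acvrl1 and the co-receptor Eng. Each group held 3 arrays, and the comparison of both viruses after 30 h in 0.5% serum asks which transcripts respond to BMP9 in these cells. The median signal per array lay between 163.65 and 192.6. Correlations of log2 signals within a group were 0.945 to 0.963 for GFP and 0.958 to 0.982 for BMP9. Between the groups they ran from 0.915 (GFP replicate 2 with BMP9 replicate 1) to 0.958 (GFP replicate 3 with BMP9 replicate 2). GFP replicate 1 correlated more closely with BMP9 replicate 1 (0.950) than with either other GFP array, so the arrays did not group by virus alone. The Gdf2 probe set read 158.9, 164.9 and 116.6 in the GFP arrays and 111.3, 148.6 and 120.5 in the BMP9 arrays, with a log2 change of -0.19 ± 0.23 (SE) and an adjusted p of 0.731. This probe set may not match the viral transcript, so its level checks neither the transgene nor the labels.

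Krt15, Hey1, Krt13 and C1qtnf3 were among the called genes with the largest fitted log2 increases, and Srpx2 among those with the largest decreases. Where a whole group was low, the fitted size depends on the offset, so these genes are not ranked. Hey1, a transcriptional repressor induced by BMP and Notch signals, rose from a signal of 56.8 ± 20.9 (SD, n = 3) in GFP to 1632 ± 590 in BMP9, a log2 change of 4.58 ± 0.32 (SE; adjusted p = 0.00112). The type I keratins Krt15 and Krt13, filament proteins of stratified epithelia, rose from 6.63 ± 1.56 to 652 ± 364 and from 19.5 ± 12.8 to 557 ± 290. Since all 3 GFP arrays were low for these genes, their increases are given as at least 13.1-fold for Hey1, 4.77-fold for Krt15 and 4.19-fold for Krt13. C1qtnf3, a secreted C1q/TNF-related protein, was at least 2.06-fold higher. Srpx2, a secreted sushi-repeat protein, fell by 3.66 ± 0.28 on the log2 scale (adjusted p = 0.0012), from 769 ± 225 to 50.9 ± 16, at least 6.62-fold lower.

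In all, 221 of the 8003 genes tested passed the threshold, 117 higher and 104 lower in BMP9, and 124 of them changed by at least 2-fold, 73 higher and 51 lower. The 3 BMP9 arrays lay outside the range of the 3 GFP arrays for every one of the 221 genes. Such separation was seen for 25.3% of all tested genes, where chance gives 10%. With the replicate number as a block, 613 genes passed, 283 higher and 330 lower, with 210 at 2-fold or more (99 higher, 111 lower), and the 221 were among the 613. Centring each array on its median gave 128 genes higher and 74 lower. Because their groups were separated, all 221 had to keep their sign in each fit that left out 1 array. Of the 56 of them named by the fixed rule, 14 were called in 6 of the 6 fits. Single arrays moved the count of genes called BMP9 against GFP: 17 genes passed without BMP9 replicate 2, 38 without BMP9 replicate 3, 44 without GFP replicate 2, 117 without BMP9 replicate 1 and 138 without GFP replicate 3.

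**Figure D1:**
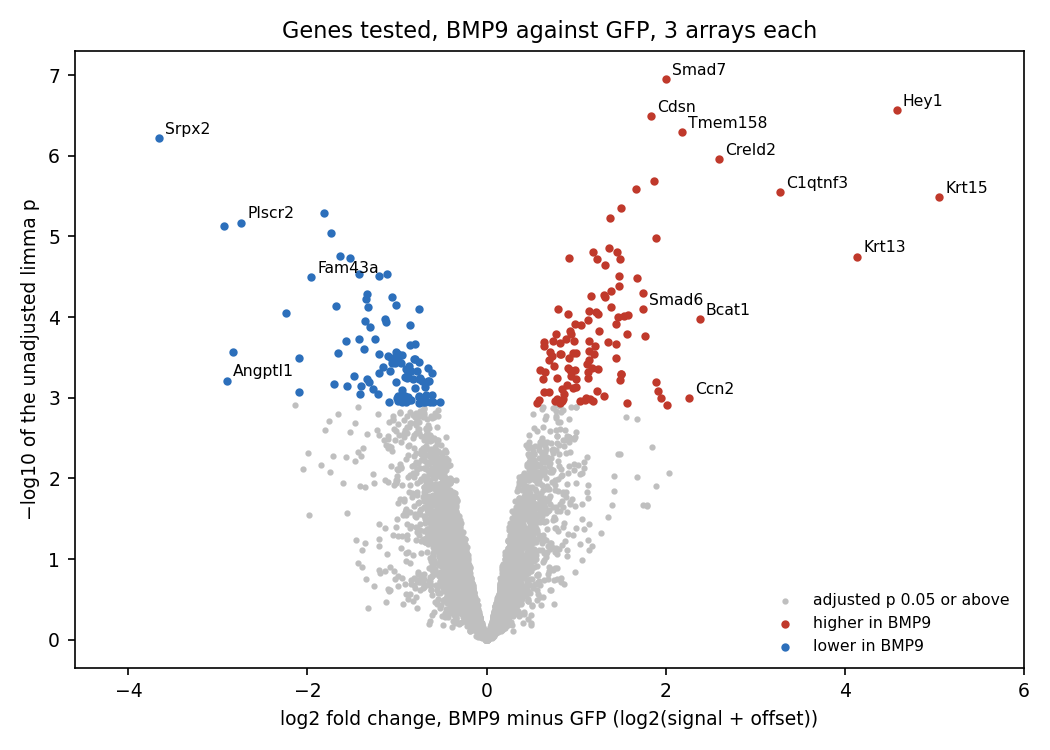
Each point is 1 of the 8003 tested genes, placed by its log2 fold change (BMP9 minus GFP, 3 arrays each) and by the negative log10 of its unadjusted limma p. The 117 genes that rose (red) and the 104 that fell (blue) at an adjusted p under 0.05 are coloured, the others are grey, and Krt15, Hey1 and Krt13 are plotted at fitted values of 5.05, 4.58 and 4.14, which depend on the offset.

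Other genes among the 15 increases taken by the rule for naming genes were Ccn2, Fmod, Mmp11, Tnfrsf12a, Unc5b, Tmem158, Cdsn and Bcat1. Ccn2, a matricellular growth factor also known as connective tissue growth factor, rose by a log2 change of 2.26 ± 0.46 (adjusted p = 0.0469), and its GFP arrays were far apart at 986.5, 836.7 and 3560. Fmod, a collagen-binding proteoglycan, rose by 1.92 ± 0.38, and the matrix protease Mmp11 by 2.01 ± 0.42 with an adjusted p of 0.0499. Tnfrsf12a, the receptor of the cytokine TWEAK, rose 3.65-fold and the netrin receptor Unc5b 3.72-fold. Tmem158 rose 4.54-fold, Cdsn, a desmosomal protein of cornified epithelium, 3.56-fold, and Bcat1, a branched-chain aminotransferase, 5.2-fold. The Cdsn probe set already read 1228 ± 126 in GFP, well above the array medians, against 4392 ± 346 in BMP9. Whether the probe sets of Cdsn, Krt15 and Krt13 also bind other transcripts was not checked. Ccn2 was called in 1 of the 6 fits that left out 1 array, as were Fmod and Mmp11, whereas Hey1, Krt15, C1qtnf3, Smad7, Creld2, Tmem158, Tnfrsf12a, Unc5b and Cdsn were called in 6 of the 6. Krt13 was called in 5 of these fits and Bcat1 in 4.

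Peli2, Angptl1, Spata13 and Plscr2 were also among the 15 decreases taken by that rule. Angptl1, a secreted angiopoietin-like protein, fell by 2.90 ± 0.55 on the log2 scale (adjusted p = 0.0379, at least 2.38-fold lower), from 290 ± 175 to 32.7 ± 31.7. Peli2, a ubiquitin ligase of Toll-like receptor signalling, was at least 1.77-fold lower, the exchange factor Spata13 3.59-fold, the phospholipid scramblase Plscr2 4.35-fold and Rab3il1 2.21-fold, each counted as a lower bound because all 3 BMP9 arrays were low. The peptide transporter Tap2, which loads MHC class I molecules, was at least 2.90-fold lower. Fitted log2 changes were -2.09 for the matrix protein Abi3bp, -1.96 for Fam43a, -1.82 for the aldo-keto reductase Akr1c14, -1.73 for Gemin8 of the SMN complex, -1.68 for the actin-associated Synpo, -1.57 for the kinase Galk2 and -1.56 for the phospholipase Plcb4. Gstm1, a glutathione transferase, changed by -1.64 ± 0.19 (adjusted p = 0.00826), on a probe set that can also bind its close paralogs. Srpx2, Peli2, Plscr2, Akr1c14 and Gemin8 were called in 6 of the 6 fits that left out 1 array, Plcb4 in 0 and Abi3bp, Angptl1, Galk2 and Tap2 in 1. Fam43a, Gstm1 and Synpo were called in 5 of these fits, and Spata13 and Rab3il1 in 3.

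Known targets of BMP and Smad signalling rose together. Of 20 members tested, 8 rose and 0 fell, and 19 had a positive log2 change, with a median of 0.94. The inhibitory Smads, which dampen the pathway that induces them, rose 4.02-fold for Smad7 (log2 change 2.01 ± 0.13, adjusted p = 0.00112) and 3.36-fold for Smad6 (1.75 ± 0.25, adjusted p = 0.0176). The inhibitors of DNA binding Id3, Id2 and Id1 rose by log2 changes of 1.19 ± 0.14, 1.19 ± 0.25 and 0.82 ± 0.14, with adjusted p values of 0.00826, 0.0482 and 0.0294. Dlx5, a homeodomain factor of bone-forming cells, rose from 394 ± 87.1 to 871 ± 62.6 (adjusted p = 0.0265), and the remaining member called was Dlx2, picked out after its value was seen, at 1.45 ± 0.24. Adjusted over the list alone, 14 members were higher and 1 lower, as were 14 and 1 with the replicate block. Leaving out 1 array, Smad7 and Hey1 were called in 6 of the 6 fits, Id3 in 5, Smad6 in 4, Dlx5 and Id1 in 2 and Id2 in 1. The list was shifted up in camera (adjusted p = 2.84e-14) and in camera with an estimated correlation (adjusted p = 0.0316). Without BMP9 replicate 2 only 2 members were called, without GFP replicate 2 or BMP9 replicate 3 it was 4, without BMP9 replicate 1 it was 5 higher and 1 lower, and camera kept its call in each of these fits.

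Genes of the unfolded protein response, the chaperones, disulfide isomerases and regulators that cells raise when protein folding in the endoplasmic reticulum is strained, had the smallest camera p of the 31 lists tested. All 27 members had a positive log2 change, 17 rose and 0 fell, and the list median was 0.97. Creld2 rose 6.04-fold, from 387 ± 65 to 2425 ± 677 (log2 change 2.59 ± 0.21, adjusted p = 0.00169). Trib3, a pseudokinase of the ATF4 branch, rose 3.21-fold (adjusted p = 0.011) and Sdf2l1 2.99-fold (adjusted p = 0.0184). Picked out after their values were seen, the abundant chaperones Hspa5 and Hsp90b1 rose by 0.92 ± 0.11 and 0.99 ± 0.15, the secreted factor Manf by 1.38 ± 0.14, and the transcription factor Ddit3 by 1.45 ± 0.25. Adjusted over the list alone, 24 members were higher. The camera adjusted p was 8.37e-27 and 0.0197 with an estimated correlation. Within the same-numbered array pairs the list median was 0.85, 1.08 and 0.81, and the members called numbered 2 without BMP9 replicate 2, 5 without BMP9 replicate 3 and 6 without GFP replicate 2, with camera keeping its call in each. With eBayes without trend 10 members were called higher and 0 lower. Leaving out 1 array, Creld2 was called in 6 of the 6 fits, Trib3 in 5 and Sdf2l1 in 4.

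**Figure D2:**
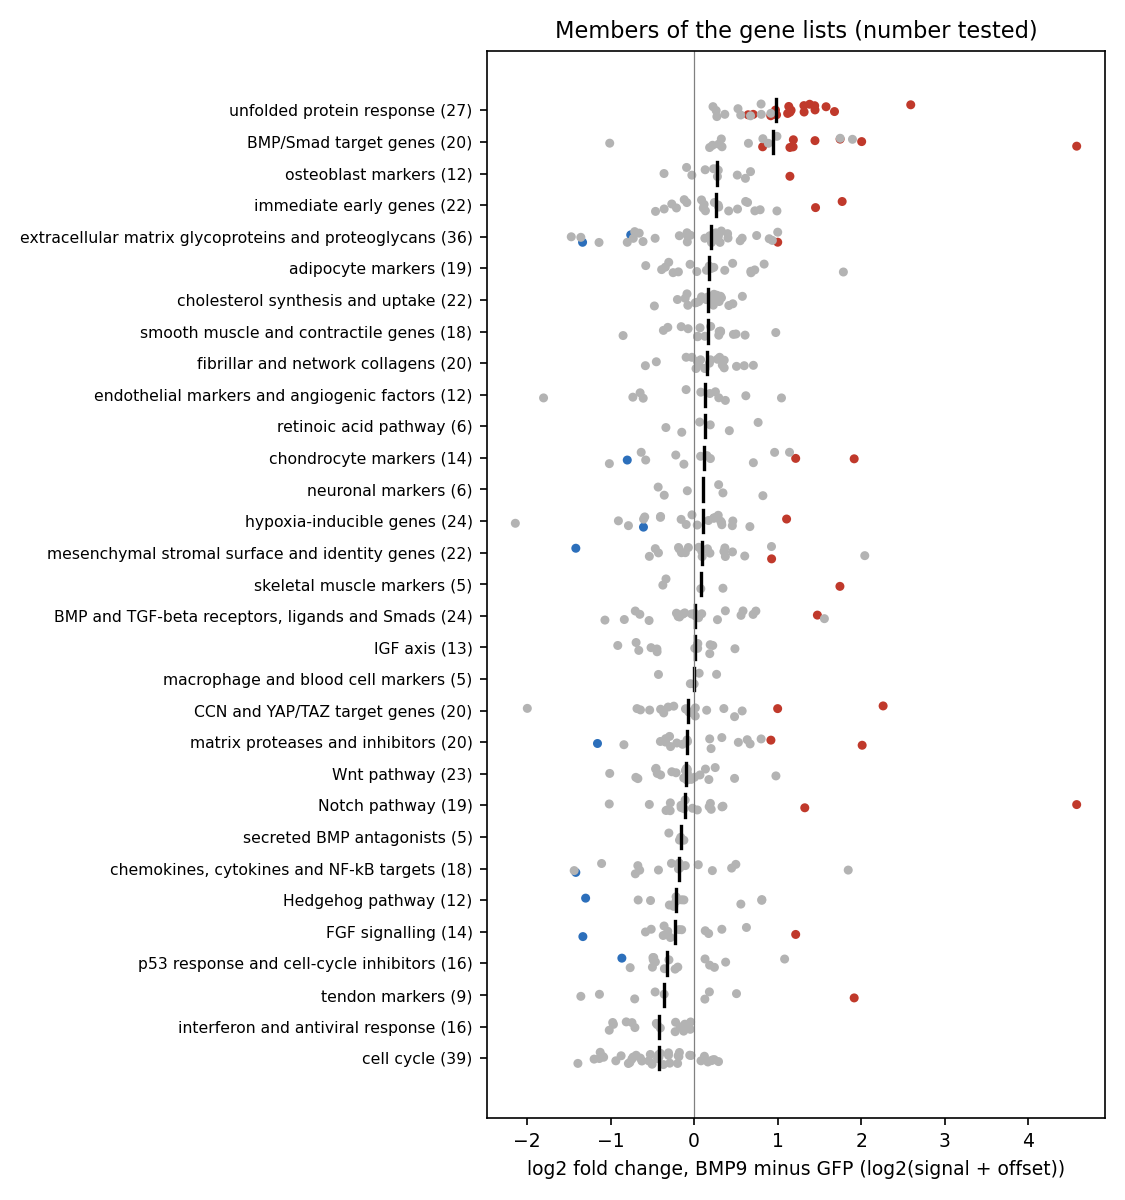
Each point is a tested member of a gene list, placed by its log2 fold change (BMP9 minus GFP, 3 arrays each), red where it rose and blue where it fell at an adjusted p under 0.05 and grey otherwise; the black bar is the list median and the number in brackets the members tested. The unfolded protein response list (median 0.97) and the BMP/Smad target list (median 0.94) lie apart from the other lists.

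Few markers of skeletal lineages passed the test at this time. Of 12 osteoblast markers tested, 1 rose, Dlx5, and 0 fell, with a list median of 0.27 (0.15 without GFP replicate 3). Without the filter on low signals 21 were measured, of which 2 were called higher and 0 lower. Col10a1, the collagen of hypertrophic cartilage, was left out by the filter. It was called higher in a fit over all probe sets (12.7 ± 4.09 to 69.8 ± 10.1), as given further below with Pth1r. There were 2 higher adjusted over the list alone and 2 with the replicate block. Camera called the list up (adjusted p = 0.0184), but its adjusted p was 0.363 with an estimated correlation, 0.0783 with quantile normalization, 0.102 with cyclic loess and 0.0564 without BMP9 replicate 1, and it ranged from 0.00414 to 0.363 over all alternatives. Sp7, a transcription factor of osteoblast commitment, read 152 ± 75.1 in GFP and 140 ± 39.5 in BMP9 (adjusted p = 0.982). Alpl, the bone alkaline phosphatase, lay below the filter on low signals, with 105.8, 99.2 and 77.4 in GFP and 98.1, 231.8 and 226.4 in BMP9 (log2 change 0.82 ± 0.35, adjusted p = 0.365 without the filter). Among 14 chondrocyte markers, Fmod and the growth factor receptor Fgfr3 rose, the latter by 1.22 ± 0.20 (adjusted p = 0.0279), and the zinc finger repressor Trps1 fell by 0.80 ± 0.13 on the log2 scale (adjusted p = 0.0271). Their median was 0.12, between -0.25 (without BMP9 replicate 1) and 0.41 (without GFP replicate 1) when 1 array was left out. Camera gave an adjusted p of 0.516, and 2 were higher and 1 lower adjusted over the list alone, and 3 higher and 2 lower with the replicate block. Sox9, the regulator of cartilage formation, had a log2 change of 0.15 ± 0.38, and the cartilage collagen Col2a1 one of 1.14 ± 0.46 with an adjusted p of 0.247, or 0.027 with the replicate block. Fmod was the 1 of 9 tendon markers that rose and 0 fell, with a list median of -0.36 although the camera direction was up (adjusted p = 0.866); adjusted over the list alone and with the block, 1 was higher and 2 were lower. The tendon median turned with single arrays, from -0.86 without GFP replicate 1 to 0.14 without GFP replicate 2. Leaving out 1 array, Trps1 was called in 3 of the 6 fits and Fgfr3 in 2. No tendon marker, and so not Fmod, was called without the filter or with eBayes without trend.

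Adipocyte and muscle markers gave few calls. None of 19 adipocyte markers passed in limma, although 5 were higher and 1 lower at an unadjusted p under 0.05 and 3 were higher with the replicate block, and the camera adjusted p was 0.176, or 0.0471 without GFP replicate 2. Pparg, the main regulator of fat cell formation, read 234 ± 110 in GFP and 401 ± 52.2 in BMP9 (adjusted p = 0.183), and Cebpa had a log2 change of 0.15 ± 0.17. The lipid-binding proteins Fabp4 and Fabp5 had log2 changes of 1.79 ± 0.64 and 0.73 ± 0.23 with adjusted p values of 0.193 and 0.141, and 0.0211 and 0.0326 with the replicate block. Further Fabp4 probe sets lay below the filter and had log2 changes of 2.13 ± 0.39, 0.96 ± 0.40 and -0.10 ± 0.30 without it. Their adjusted p values in limma were 0.0585, 0.356 and 0.94. Scd1, a fatty acid desaturase, had an adjusted p of 0.155, or 0.0475 with the block. In the skeletal muscle list 1 of 5 members rose and 0 fell, the transcription factor Mef2c at 3.35-fold (adjusted p = 0.0148), with a camera adjusted p of 0.477. Mef2c was called in 4 of the 6 fits that left out 1 array. The muscle regulator Myod1 lay below the filter at 58.3 ± 8.96 in GFP and 47.6 ± 13.5 in BMP9. Of 18 smooth muscle and contractile genes 0 passed in limma, 3 were higher and 0 lower at an unadjusted p under 0.05, 1 was higher with the replicate block (Csrp2, block adjusted p = 0.0111), and camera gave an adjusted p of 0.176, or 0.0415 without BMP9 replicate 1. In counts adjusted over the list alone, 0 adipocyte and 0 smooth muscle genes passed, and Mef2c was the 1 skeletal muscle gene. Smooth muscle actin, Acta2, read 10067 ± 1146 in GFP and 12502 ± 574 in BMP9 (adjusted p = 0.209).

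Genes of the extracellular matrix changed in both directions. Among 36 matrix glycoproteins and proteoglycans, the microfibril protein Mfap5 rose 2-fold (adjusted p = 0.0409) and the basement membrane proteins Fbln2 and Lamb1 fell by 0.76 ± 0.11 and 1.33 ± 0.25 on the log2 scale, with adjusted p values of 0.0176 and 0.0372. The same list had 1 member higher and 7 lower adjusted over the list alone, and 2 higher and 9 lower with the replicate block. Its median was 0.20, or 0.02 without GFP replicate 1, and its mean -0.04, and camera gave an adjusted p of 0.742. Mfap5 was not called with quantile normalization or cyclic loess, where the list median was 0.092 and 0.096. Of 20 fibrillar and network collagens 0 passed in limma, 4 being higher and 0 lower at an unadjusted p under 0.05 and 1 lower with the replicate block, while 16 had a positive log2 change. Camera called the collagens up (adjusted p = 0.0412), a call lost with an estimated correlation (adjusted p = 0.734), with the replicate block (adjusted p = 0.0525) and with either quantile normalization (adjusted p = 0.126) or cyclic loess (adjusted p = 0.184). It was also lost without the filter (adjusted p = 0.112), with the 60th percentile filter (0.0854), with array weights (0.0925), with eBayes without trend (0.0507) and without both replicate 1 arrays (0.0781), and the range over all alternatives was 0.0079 to 0.734. Single arrays also ended that call, with adjusted p values of 0.311 without GFP replicate 3, 0.219 without BMP9 replicate 1 and 0.0592 without BMP9 replicate 3. The members with the smallest p were Col6a3 at 0.60 ± 0.17 and Col9a1 at 0.71 ± 0.25. Among 20 matrix proteases and inhibitors, Mmp11 and the urokinase receptor Plaur (0.92 ± 0.16, adjusted p = 0.0304) rose and the membrane protease Mmp16 fell by 1.16 ± 0.21 on the log2 scale (adjusted p = 0.034). That list had a median of -0.08, or 0.06 without GFP replicate 2, and a mean of 0.11 (camera adjusted p = 0.477), with 4 members higher and 2 lower under the replicate block. Of 22 mesenchymal stromal genes the transcription factor Snai1 rose 1.9-fold (adjusted p = 0.0348) and the adhesion molecule Vcam1 fell by 1.42 ± 0.29 on the log2 scale (adjusted p = 0.0449), with a camera adjusted p of 0.176. With the replicate block 4 of these were higher and 1 lower. In counts adjusted over the list alone, 3 proteases and inhibitors were higher and 1 lower, 4 stromal genes were higher and 1 lower, and 0 collagens passed. As means over their probe sets, Mmp16 and Vcam1 were not called (adjusted p = 0.0515 and 0.0658). Without the filter 0 proteases and inhibitors and 0 stromal genes were called, and of the glycoproteins and proteoglycans 0 were higher and 1 lower. With eBayes without trend 1 protease or inhibitor was higher and 0 lower. In that fit 0 stromal genes were called, and 0 glycoproteins and proteoglycans were higher and 1 lower. Leaving out 1 array, Fbln2 was called in 3 of the 6 fits and Lamb1, Mfap5, Mmp16, Plaur and Snai1 in 1.

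Components of growth factor pathways were tested next to the BMP targets. Inhba, the subunit of activin A, was the 1 member of 24 BMP and TGF-beta ligands, receptors and Smads that rose (2.78-fold, adjusted p = 0.0109), and 0 fell, against 3 higher and 2 lower with the replicate block. Eng read 531 ± 17.8 and 693 ± 65.7 (adjusted p = 0.203), and Acvrl1 lay below the filter at 67 ± 17.2 and 60.4 ± 23.7. Of 5 secreted BMP antagonists 0 passed in limma and 1 was lower at an unadjusted p under 0.05, with 0 called under the replicate block; Twsg1 and Fstl1 had log2 changes of -0.30 ± 0.13 and -0.12 ± 0.16. In the Notch list 2 of 19 members rose, Hey1, also a BMP target, and Lfng, a glycosyltransferase that modifies Notch (2.51-fold, adjusted p = 0.0148). The median of that list was -0.11, or 0.06 without GFP replicate 2, and its mean 0.20, with 2 higher and 1 lower under the replicate block. Of 23 Wnt pathway genes 0 passed in limma, with 1 higher and 3 lower at an unadjusted p under 0.05 and the same numbers under the replicate block, among them the receptors Fzd7 at 0.98 ± 0.24 and Fzd8 at -0.70 ± 0.21, with block adjusted p values of 0.0101 and 0.0358. Gas1, a co-receptor of Hedgehog ligands, fell by 1.30 ± 0.20 on the log2 scale (adjusted p = 0.0216) as 1 of 12 members of its pathway, where 1 was higher and 2 were lower with the replicate block. The 3 probe sets of Gas1 ran from -1.43 to -0.14 with 2 of them called, and as a mean over them Gas1 was not called (adjusted p = 0.0839). In the CCN and YAP/TAZ list of 20 genes, the matricellular proteins Ccn2 and Ccn1 rose, the latter 2-fold (adjusted p = 0.0376), with 3 higher and 3 lower under the replicate block. No member of that list was called higher without the filter, with eBayes without trend or without GFP replicate 2 or any 1 of the BMP9 arrays. Among 14 FGF signalling genes Fgfr3 rose and the ligand Fgf7 fell by 1.33 ± 0.18 on the log2 scale (adjusted p = 0.0148), with 1 higher and 2 lower under the replicate block. Leaving out 1 array, Inhba was called in 4 of the 6 fits, Gas1, Fgf7 and Lfng in 3 and Ccn1 in 2.

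Neither the IGF axis nor the retinoic acid pathway held a called gene in limma. For 13 IGF axis genes 1 was higher and 1 lower at an unadjusted p under 0.05, and 1 was lower with the replicate block, the clearance receptor Igf2r at -0.69 ± 0.15 (adjusted p = 0.0564, block adjusted p = 0.0356). Igfbp7 stood at 0.49 ± 0.14 and Igf2 at -0.44 ± 0.38, and the list had a median of 0.01, or -0.25 without BMP9 replicate 3, and a mean of -0.19. For 6 retinoic acid genes 1 was higher and 0 lower at an unadjusted p under 0.05 and 0 with the block, with Dhrs3 at 0.77 ± 0.25 and Rarg at 0.42 ± 0.23. Adjusted over the list alone, the members higher and lower numbered 4 and 3 for the BMP and TGF-beta components, 2 and 0 for Notch, 1 and 2 for Hedgehog, 2 and 4 for the CCN and YAP/TAZ list, 1 and 2 for FGF and 1 and 1 for the IGF axis, and 0 passed for the secreted antagonists, the Wnt pathway or the retinoic acid pathway. Camera adjusted p values were 0.477 for the BMP and TGF-beta components, the secreted antagonists, the Wnt pathway and the retinoic acid pathway, 0.506 for Hedgehog, 0.614 for FGF, 0.692 for Notch and 0.766 for both the CCN and YAP/TAZ list and the IGF axis.

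Camera called the immediate early genes up and the interferon and antiviral response genes down, in both cases with the preset correlation alone. Of 22 immediate early genes 2 rose and 0 fell: Klf10, a Krüppel-like repressor induced by TGF-beta, at 2.74-fold (adjusted p = 0.00826), and Atf3, a stress-induced transcription factor, from 74.3 ± 13.5 to 288 ± 102, at least 2.4-fold higher (adjusted p = 0.0248). Camera called this list up (adjusted p = 0.00697), with an adjusted p of 0.649 with an estimated correlation, and 6 members were higher with the replicate block and 3 adjusted over the list alone. The immediate early list had an adjusted p of 0.12 with the 60th percentile filter and values from 0.000105 to 0.649 over all alternatives. Leaving out 1 array, Klf10 was called in 5 of the 6 fits and Atf3 in 3. All 16 interferon and antiviral response genes tested had a negative log2 change, with a median of -0.42, and camera called the list down (adjusted p = 0.0125). None of them passed singly in limma; 5 were lower and 0 higher at an unadjusted p under 0.05, 3 were lower with the replicate block and 2 adjusted over the list alone. The transcription factor Irf1 stood at -1.02 ± 0.24 and the interferon-induced GTPase Irgm1 at -0.97 ± 0.24, with block adjusted p values of 0.018 and 0.0246. The shift of the interferon list had an adjusted p of 0.734 with an estimated correlation, 0.0649 with the 60th percentile filter, 0.105 without GFP replicate 2 and 0.174 without BMP9 replicate 1, within a range of 0.00072 to 0.734 over all alternatives. Its median shrank to -0.15 without GFP replicate 2 and to -0.22 without BMP9 replicate 1. On this list the replicate 1 arrays of both groups read lower than the others, by a median log2 difference of -0.51 (camera adjusted p = 0.0003, or 0.742 with an estimated correlation). Among 18 chemokines, cytokines and NF-kB targets Vcam1 fell and 0 rose, with 1 higher and 3 lower under the replicate block, 1 higher and 2 lower adjusted over the list alone and a camera adjusted p of 0.277.

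Cell cycle genes had a median log2 change of -0.43 over 39 members, of which 7 were positive, yet 0 passed in limma and 0 did so at an unadjusted p under 0.05. The members with the smallest p were the spindle motor Kif11 at -0.79 ± 0.36 and the replication helicase subunit Mcm4 at 0.29 ± 0.15. Camera gave an adjusted p of 0.176, or 0.865 with an estimated correlation, 0.0341 after median centring and 0.000305 with the replicate block, under which 4 members were lower. Single arrays moved this shift both ways: the median was -0.91 without GFP replicate 1 (adjusted p = 5.07e-06) and -0.70 without BMP9 replicate 2 (0.00198). It was -0.04 without BMP9 replicate 1 (0.863) and -0.11 without GFP replicate 3 (0.763). With array weights it was -0.27. Without both replicate 1 arrays, a fit chosen after the data were seen, the median was -0.47 and the adjusted p 0.000142. Over all alternatives the adjusted p ranged from 5.07e-06 to 0.865. The replicate 1 arrays of both groups read lower on this list than the others, by a median log2 difference of -1.25, and the medians within the same-numbered pairs were -0.43, -0.04 and -0.99. Of 16 p53 response genes and cell-cycle inhibitors, Cdkn2c, an inhibitor of cyclin-dependent kinases, fell by 0.86 ± 0.18 on the log2 scale (adjusted p = 0.0482) and 0 rose (camera adjusted p = 0.176, or 0.0327 without GFP replicate 1), against 1 higher and 2 lower with the replicate block. Among 24 hypoxia-inducible genes Hif1a, the oxygen-regulated transcription factor itself, fell by 0.61 ± 0.11 on the log2 scale (adjusted p = 0.0353) and P4ha2, a collagen prolyl hydroxylase, rose 2.15-fold (adjusted p = 0.0469), with 2 higher and 5 lower under the replicate block. The hypoxia list had a median of 0.10 (0.03 without GFP replicate 3 and 0.19 without GFP replicate 1), a mean of -0.08 and a camera adjusted p of 0.651. Of 22 cholesterol synthesis genes 0 passed in limma, 1 being lower and 0 higher at an unadjusted p under 0.05 and 0 with the block, with Insig2 at -0.48 ± 0.19, Nsdhl at 0.42 ± 0.28 and a camera adjusted p of 0.277, or 0.0418 without GFP replicate 3. Adjusted over the list alone, 2 hypoxia-inducible genes were higher and 4 lower, 1 p53 response gene was higher and 4 lower, and 0 cell cycle and 0 cholesterol genes passed. Hif1a, Vcam1 and Cdkn2c were called in 0 of the 6 fits that left out 1 array and P4ha2 in 1. Neither Hif1a nor Cdkn2c was called with median centring, without the filter or with eBayes without trend.

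Markers of other cell types were included to look for admixed cells. Of 12 endothelial and angiogenic genes 0 passed in limma, with 2 higher and 3 lower at an unadjusted p under 0.05 and 1 higher and 2 lower with the replicate block, including the peptide ligand Apln at 0.62 ± 0.13 (adjusted p = 0.0529, block adjusted p = 0.036) and the lipase inhibitor Angptl4, low on all 3 BMP9 arrays and at least 1.81-fold below its mean GFP signal of 210 ± 97.6 (adjusted p = 0.0708, block adjusted p = 0.0311). That list had a median of 0.13, or 0.04 without BMP9 replicate 3, a mean of -0.09 and a camera adjusted p of 0.742. Of 6 neuronal markers 0 passed in limma; 1 was higher at an unadjusted p under 0.05 and with the block, Stmn2 at 0.82 ± 0.19 (block adjusted p = 0.0439), Map2 stood at -0.43 ± 0.25, and camera gave 0.477. Of 5 macrophage and blood cell markers 0 passed in limma, at an unadjusted p under 0.05 or with the block; Cd14 stood at -0.43 ± 0.22 and Csf1r at 0.27 ± 0.15, with a camera adjusted p of 0.85. In counts adjusted over the list alone, 1 endothelial gene was higher and 3 lower, 1 neuronal gene was higher and 0 macrophage genes passed. Only 2 epithelial markers were above the filter, Cldn3 at 0.29 ± 0.19 and Krt8 at -0.06 ± 0.21, and the list was not tested. Beta-actin, Actb, read 14608 ± 1348 in GFP and 16573 ± 1216 in BMP9, a log2 change of 0.18 ± 0.11 with an adjusted p of 0.461.

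**Figure D3:**
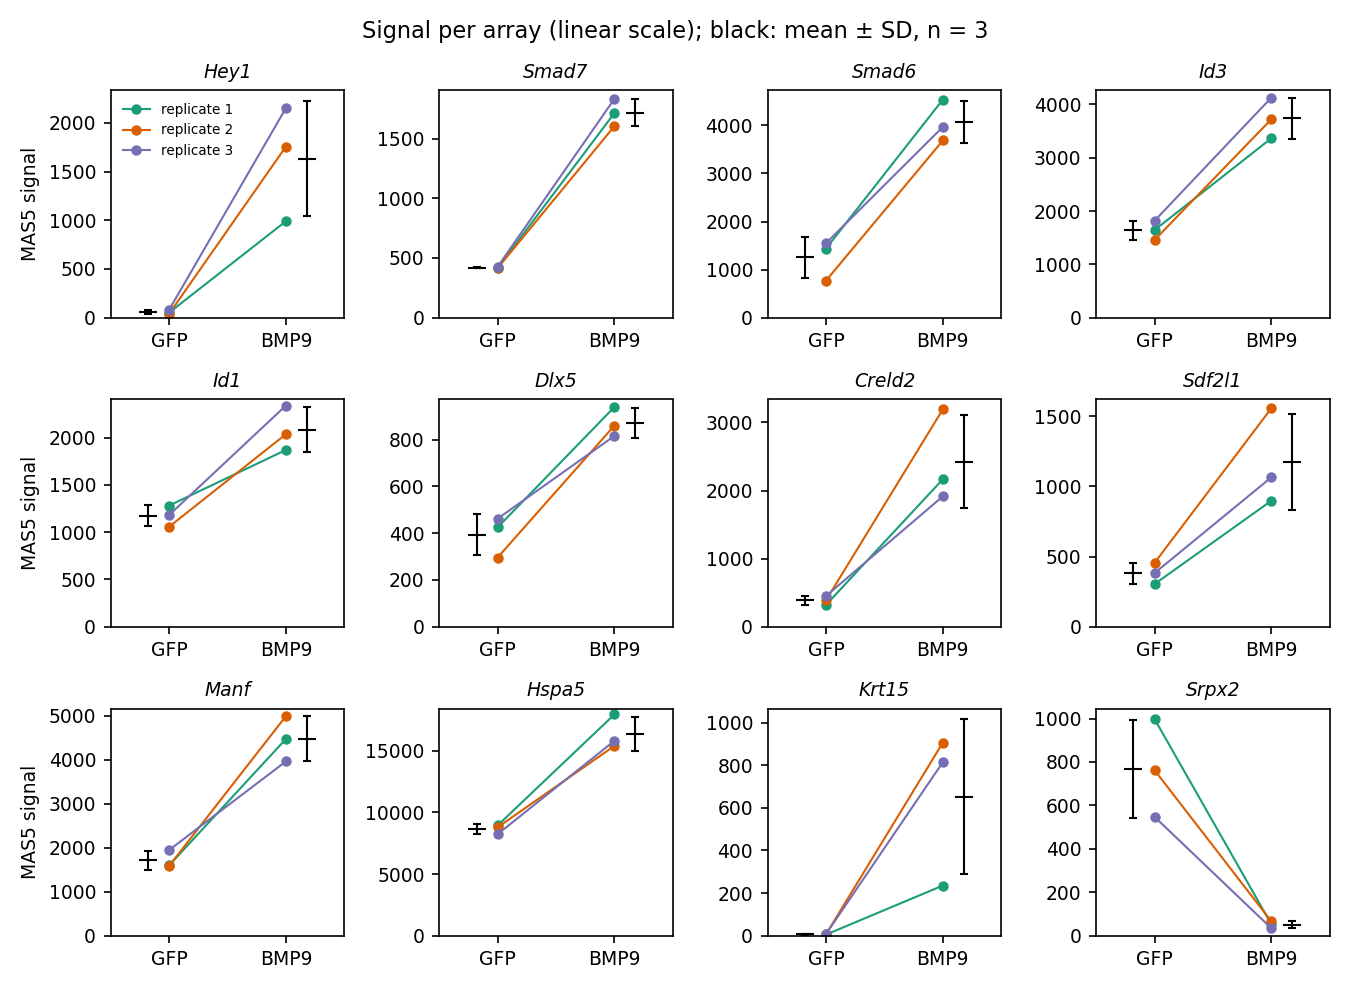
Signals of 12 genes on each array on a linear axis, with coloured lines joining the GFP and BMP9 arrays of the same replicate number and black marks for the mean and SD of each group (n = 3). Hey1, Smad7, Smad6, Id3, Id1, Dlx5, Creld2, Sdf2l1, Manf, Hspa5 and Krt15 lie higher on all 3 BMP9 arrays and Srpx2 lower.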

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

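The tests of the unfolded protein response list and the test of RNA quality were chosen only after the results they bear on had been seen.

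Low-signal probe sets left out by the filter held 4 named genes that limma called higher in BMP9 when fitted over all probe sets. Their fitted log2 changes, whose size depends on the offset because all GFP signals lay below the 40th percentile, were 3.34 for Pth1r, the parathyroid hormone receptor (4.6 ± 2.82 to 157 ± 76.5), 2.18 for the antimicrobial peptide gene Camp (15.5 ± 4.77 to 107 ± 12.3), 2.11 for Samd11 (7.57 ± 6.91 to 65.1 ± 14.3) and 1.79 for Col10a1, the collagen of hypertrophic cartilage (12.7 ± 4.09 to 69.8 ± 10.1). Their adjusted p values were 0.0211, 0.0211, 0.0429 and 0.034. Samd11 and Col10a1 lay below that percentile on all 6 arrays, so the size of their increases cannot be given, although every BMP9 signal lay above every GFP signal. In the same fit 9 named probe sets were lower in BMP9, with the smallest adjusted p for Medag (116 ± 12.4 to 14.4 ± 5.03, adjusted p = 0.0163). The others were those of Atp13a2, Nat8f4, Zfp235, Lrig1, Rag1, Il4ra, Chil1 and Runx1t1.

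The real split of the arrays gave 338 probe sets, 221 genes and 124 genes at 2-fold, and the highest count among the other splits was 0 for each, so that 1 of the 10 splits gave as many. For the gene lists, the real split called 6 and 6 of the 10 splits called as many, with 11 as the highest other. With 10 splits the share cannot fall under 0.05. Preset camera thus also called lists in splits that mix the groups. Each mixed split has more BMP9 arrays on 1 side than on the other, so part of the BMP9 difference remains in it. In every mixed split the medians of the unfolded protein response and BMP/Smad target lists were higher on the side with more BMP9 arrays. List calls in these splits therefore cannot be counted as false. The highest absolute list medians in mixed splits were 0.404 for the unfolded protein response and 0.381 for the BMP/Smad targets. Lying below the real medians of 0.97 and 0.94 is what mixing alone would give, so these medians decide nothing. Among the 4 splits that part all 3 numbered pairs, the other splits gave 0 genes. Mixing GFP and BMP9 arrays also widens the spread within a side for genes that differ between the groups. Counts of 0 in mixed splits are therefore partly set by the design.

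Genes of the unfolded protein response were higher in BMP9. The median of 0.97 lay above the highest of 10000 random lists matched on mean expression, 0.256, which argues against an array-wide or intensity-dependent shift. The lowest median within a numbered pair was 0.806, which argues against the replicate 1 arrays as the source. The load of any secreted viral product, rather than BMP9 signalling, could raise the same genes; the design holds no virus with another secreted protein, so that for the median of 0.975 these explanations cannot be told apart.

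Krt15 and Krt13 were higher in BMP9, from very low signals in GFP, and epithelial cells in the cultures are a candidate source. Without the filter the 20 measured epithelial markers had a median log2 change of -0.147 (quartiles -0.31 and 0.18), 0 were called by limma and 1 was higher at an unadjusted p under 0.05, Pkp1, which argues against such cells. The levels of keratins of simple epithelia were 36.7 ± 6.01 in GFP and 21.7 ± 22.2 in BMP9 for Krt18 and 196 ± 22.8 and 190 ± 42.1 for Krt8. For keratins of stratified epithelia they were 51.9 ± 39.4 and 40.5 ± 30.9 for Krt5 and 111 ± 21.8 and 91.9 ± 18.4 for Krt14. A programme of stratified epithelium genes stays open: 0% of 32 further members of a list written after part of the called genes had been seen passed in limma, which allows up to 10.9% (exact binomial, 95%), and 2 were higher at an unadjusted p under 0.05. Left out of these 32 were Krt15, Krt13, Cdsn, Gjb5 and Anxa8, which had been seen as called higher. The limit treats genes as independent, and a gene not called may have changed: Pkp1 went from 39.4 ± 4.49 to 201 ± 118 without a call.

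Both replicate 1 arrays deviated together, and 663 probe sets differed between them and the other arrays with the group as a term, 249 higher and 414 lower. That contrast was chosen because these arrays deviated together in the same data. Its counts and p-values therefore describe the deviation and are no separate test of it. The rule set for RNA quality was not met, since for 0 of the 2 control transcripts, actin and Gapdh, did both arrays lie outside the others on 1 side in the difference of 3' and 5' signal. That does not decide the question, because BMP9 replicate 1 had the highest log2 difference of all arrays for actin (0.239) and for Gapdh (-0.281). GFP replicate 1 stood at 0.194 for actin, just under GFP replicate 3 (0.201), but at -0.46 for Gapdh, below all arrays except BMP9 replicate 2 (-0.494). Intensity-dependent differences are argued against, since the correlation of the deviations was 0.529 after cyclic loess. A different growth state of these cultures may be involved: the cell cycle list was lower by a median of -1.25, with a camera adjusted p of 3.87e-24, but 0.742 with an estimated correlation, which leaves it open.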

How the results depend on the processing

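Leaving out both replicate 1 arrays was chosen after the data were seen; the other alternatives were planned. All 221 called genes kept their sign in every alternative in which they were tested (201 with the 60th percentile filter). Since their groups were separated, only the normalizations and the mean over a gene's probe sets could have turned a sign. The other alternatives could not, so the kept signs there are no evidence. Without the filter on low values 145 probe sets called BMP9 against GFP, 107 genes called and 80 genes called with at least 2-fold change passed, with eBayes without trend 156 probe sets and 99 genes, with array weights 736, 441 and 188, and with the replicate block 990, 613 and 210. Of the 221 genes, 99 were still called without the filter, 97 with eBayes without trend and 221 with array weights and with the block. Without the filter more probe sets were tested; the cause was not tested for the others. Leaving out both replicate 1 arrays gave 473 probe sets, 309 genes, 192 genes at 2-fold and 8 lists. Limma's treat with a minimum of 1.5-fold, a stricter test by construction, called 14 genes. Lists called numbered 3 with the 60th percentile filter, 2 by camera with estimated correlation and 3 by fry, against 6; under that filter 5 lists had too few members and have no value. Leaving out 1 array at a time gave 23 to 302 probe sets, 17 to 201 genes, 17 to 144 genes at 2-fold and 4 to 8 lists, with fewer samples in each fit. Of the 56 called genes named by the fixed rule, 14 were called in 6 of these 6 fits and 4 in 0. For named genes, 1515 values stayed on their side of the threshold, 29 passed it, 208 no longer passed and 14 reversed, and for lists 582, 11, 22 and 0. The reversed values were all of uncalled genes near 0. Krt8 (-0.06) read 0.023 with quantile normalization, 0.021 with median centring, 0.011 with cyclic loess and 0.079 without both replicate 1 arrays, and -0.22 (without BMP9 replicate 3) to 0.070 (without BMP9 replicate 1) when 1 array was left out. Sp7 (-0.03) read 0.045, 0.053 and 0.041 under the same normalizations and -0.42 (without GFP replicate 1) to 0.31 (without GFP replicate 2). Sox9 (0.15) lay between -0.25 (without BMP9 replicate 1) and 0.46 (without GFP replicate 1). The replicate block changed no call of a named gene or list other than those given with it. Signals near the background have the widest relative spread, so changes of genes under the filter are the least certain.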

Other observations

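The list of ATF4-regulated genes was written, and its test chosen, only after part of the called genes had been seen; the prediction for its further members was written before their values were.

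Genes that the transcription factor ATF4 induces under stress, many of them enzymes of amino acid supply and tRNA charging, tended to lie higher in BMP9. Bcat1 (2.38 ± 0.35, adjusted p = 0.0194), Got1, the cytosolic aspartate aminotransferase (1.49 ± 0.18, adjusted p = 0.00826), and the stress genes Ddit3, Trib3 and Chac1 were called in limma. The hypothesis that the amino acid arm of the response rises as well as its chaperone arm was tested on the 24 further members that had not been seen and are not in the unfolded protein response list. Their median log2 change was 0.51, 22 were positive, 17 lay above 0.3, and 2, the synthetases Wars and Aars, were called higher against 0 lower. Apart from these 2, 20 of 22 were positive and 15 lay above 0.3. The further members with a negative log2 change were Ddit4 at -0.91 ± 0.34 and the enzyme Psat1 at -0.02 ± 0.23, and the enzyme Phgdh stood at 0.15 ± 0.32. Camera gave an adjusted p of 1.33e-07, but the p was 0.113 with an estimated correlation, so that genes moving together in these 6 arrays remain a possible explanation. With the replicate block 6 further members were higher and 1 lower.

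Differences between the replicate 1 arrays and the others were large in named genes. The contrast was chosen from these same data, so its p-values are descriptive. The contractile genes Tagln and Myl9 had log2 differences of -3.24 and -2.15, with adjusted p values of 0.000602 and 0.000765 in limma with the group as a term, and the mitotic cyclin Ccnb2 had one of -2.43 (adjusted p = 0.00213). Camera called 7 of the 31 lists on this contrast, lower for the cell cycle, interferon, chemokine, smooth muscle and matrix glycoprotein lists and higher for the cholesterol and collagen lists, and 0 with an estimated correlation. Among the genes higher on these arrays were Cdh13 at 1.33 and Ablim1 at 1.70.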
